A study of Mus musculus with 4 samples.

How the data were processed

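Single-cell RNA sequencing had been made from mouse yolk sacs dissected at embryonic day 8.5. Per the labels, the tissue was dissociated, living cells were sorted, and 10x 3' libraries were prepared. Each library pooled 2 yolk sacs, and each genotype had 2 libraries. The control genotype, CAG-Cre/+;R26lsl-rtTA-EGFP/+, carries a Cre recombinase and a Cre-activated reverse tetracycline transactivator (rtTA) with EGFP. The Sp8 gain-of-function genotype, called Sp8_GOF here, carries in addition the doxycycline-dependent allele tet-O-Sp8-EGFP/+. The labels give doxycycline from day 5.5 for all 4 libraries, with end days of 8.5 and 8.6 for the control libraries and 8.7 and 8.8 for the Sp8_GOF libraries, while the series design gives day 8.5 for the embryos of every library. Both were taken as written, so whether dosing or age differed between genotypes was left open.

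The deposited files hold raw UMI counts per gene and barcode, already filtered to cell barcodes by the authors' pipeline. Per the submitters' processing notes this was Cell Ranger with the builds GRCm38 and mm10; the software version, and the sequences of the construct features, are not given in the sources used here. The counts cover 32287 features, of which 2 are constructs: SP8-IRES2-EGFP, called the construct below, and rtTA-EGFP. Both feature names include EGFP and an SV40 polyadenylation signal; how reads from shared sequence were assigned is not given in the sources used here. The Sp8 gene is a separate feature, and reads from the Sp8 coding part of the construct can be counted under it.

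Barcodes with at least 1000 detected genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library as the share of simulated doublets among the 60 nearest neighbours of a cell, and the highest-scoring cells were removed at 0.8% per 1000 barcodes, which took 128 and 136 cells from the control libraries and 158 and 75 from the Sp8_GOF libraries. The remaining 14947 cells were clustered together without batch integration, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1. The construct features, Sp8, Sp5 and mitochondrial genes were left out of the clustering. The 24 clusters were named from 14 marker lists fixed before the data were examined, and called "X-like". The numerical naming thresholds (a marker score of at least 0.65 and a margin of 0.1 over the next list) were set afterwards. Where another list came within the margin, the markers among the cluster's leading genes decided, or it stayed unnamed. The yolk sac endoderm-like cluster, at 1.0 against 0.988 for parietal endoderm, was named in this way. A name was dropped where the top 10 genes held more markers of another list. The lists for megakaryocytes, erythro-myeloid progenitors and macrophages were joined into 1 haematopoietic progenitor class. Clusters 9, 16, 17 and 19 stayed unnamed.

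Raw counts were summed per library and class, since cells are not replicates. Classes with at least 30 cells in every library were compared between genotypes with edgeR's quasi-likelihood test (TMM factors, filterByExpr, robust moderation), on 2 against 2 libraries, with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. All adjusted p-values of single genes come from edgeR unless DESeq2 is named. Standard errors are the absolute log2 fold change divided by the square root of F. Values of single genes as counts scaled to a common library total (CPM) in a tested class use TMM-scaled library sizes; CPM of the construct per library and class use plain totals. Each of 34 gene lists with at least 5 measured genes was tested with camera from limma at a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry were alternatives. Differences of effect between classes were tested as interactions with library as a block. Shares of cells carry exact Clopper-Pearson intervals at 95% confidence and exact two-sided permutation tests over libraries. CPM intervals are exact Poisson intervals. These intervals cover counting error only. For shares of cells with a UMI, cells were thinned to 10000 UMIs and shallower cells left out (60 and 43 control cells, 102 and 30 Sp8_GOF cells). A count of 0 was taken to allow up to 3 counts.

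The p-values of single genes between genotypes measure the spread between libraries, each a pool of 2 yolk sacs. In fits by embryo the unit is the embryo. Those of camera at the preset correlation set a list's genes against the other genes, and are too small where list members vary together. For mitochondrial transcripts of erythroid-like cells the estimated correlation was 0.61. Nothing in the labels ties a replicate number to a litter or day. Where a library was left out, the genotype with 1 library was assumed to vary like the other. The alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, the DESeq2 Wald test, no robust moderation, the replicate number as a block, each library left out, doublets kept, a stricter cell filter (2000 genes, 10% mitochondrial UMIs), doubled clustering resolution, classes by highest marker score per cell, counts thinned to the shallowest library, equal numbers of cells, and genes low in CPM against another class, and so open to free RNA, left out.

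Some comparisons were chosen after the data were examined. The yolk sac endoderm-like class had 17 to 83 cells per library and was fitted with a minimum of 15 cells, as was its interaction with the mesoderm-like class. The erythroid against mesoderm interaction, fits without clusters that held no control cell, sums per embryo, and the comparison of transgene-high with transgene-low cells were also added. Embryos were told apart by Xist and Y-linked transcripts, since every library held cells of both kinds and 2 yolk sacs; sums per embryo used classes with at least 10 cells per embryo and sex as a term.

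The rule for named genes, fixed before the data were examined, took Sp8 and Sp5 in each class, the genes past the threshold with the largest changes, and the 4 members with the smallest p of each gene list described. No gene passed the threshold in the genotype comparisons of single classes, so the genes named there come from the lists. Genes named outside this rule are said to be so. Some results that the rule would name were left out of the text.

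The tests were checked on simulated counts drawn from the real means and library sizes, with 50 changed genes at each fold. For erythroid-like cells, with 15557 simulated genes tested, 0% of genes changed 1.5-fold, 2% changed 2-fold, 46% changed 4-fold and 70% changed 8-fold were recovered. For mesoderm-like cells, with 12802 genes tested, the shares were 2%, 32%, 72% and 94%. For transgene-high against transgene-low cells, with 12091 genes tested, they were 36%, 56%, 82% and 96%. Unchanged simulated genes called were 6, 25 and 16 in these comparisons. Each gene was drawn independently, so the simulation lacks shifts shared by many genes between libraries of 1 genotype. In the real erythroid-like fit the construct at a log2 fold change of 4.83 and Sp8 at 5.97 did not pass. The erythroid shares therefore do not carry over to the real data, and a count of 0 genes does not show that large changes were absent.

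Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Gene positions are those of GRCm38 in the GENCODE vM21 annotation, matched by gene identifier. Transcripts of near-identical copies, such as the haemoglobin genes Hba-a1 and Hba-a2, cannot be assigned with certainty.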

Results

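The transcriptomes of single yolk sac cells were compared between mouse embryos with doxycycline-induced Sp8 and controls lacking the inducible allele. Sp8 encodes a zinc-finger transcription factor, and the series asks how it and its relative Sp5 bear on the formation of primary cilia, the microtubule-based sensory projections of most cell types. The 2 control libraries held 4033 and 4226 barcodes with 96876367 and 127862167 UMIs, and the 2 Sp8_GOF libraries 4485 and 3093 barcodes with 117483744 and 96199031 UMIs. After filtering and doublet removal 3837, 3901, 4236 and 2973 cells remained, with median depths of 23012, 29698, 25355 and 30138 UMIs. Libraries of 1 genotype differed by more than sampling noise: the chi-square per gene was 49.8 between the control libraries and 498 between the Sp8_GOF libraries, against 230 to 481 between libraries of different genotype.

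Among the classes given here, transcripts of the induced SP8-IRES2-EGFP construct were highest in primitive erythroid-like cells. Progenitor-like blood cells did not stand above the classes outside the blood. In primitive erythroid-like cells, the first red cells of the embryo, they reached 326 and 79.6 CPM in the Sp8_GOF libraries against 6.56 and 7.54 CPM in the control libraries. In extraembryonic mesoderm-like cells, the inner mesodermal layer of the yolk sac, the values were 36.5 and 23.2 CPM against 6.53 and 9.13 CPM. In haematopoietic progenitor-like cells they were 31.5 and 27.1 CPM against 6.62 and 9.77 CPM, in endothelium-like cells 33.0 and 16.2 CPM against 9.19 and 15.98 CPM. In yolk sac endoderm-like cells, the absorptive epithelium facing the maternal side, they were 30.04 and 41.8 CPM against 0 and 12.4 CPM. Trophoblast-like cells held 19.2 CPM in Sp8_GOF replicate 2 against 4.37 and 2.93 CPM in the control libraries.

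Over all cells the construct took 25821 and 4916 UMIs in the Sp8_GOF libraries (233 and 53.1 CPM) and 602 and 977 UMIs in the control libraries (6.52 and 8.05 CPM). At 10000 UMIs per cell, 53.7% (Clopper-Pearson interval 52.2 to 55.3) and 23.2% (21.7 to 24.8) of Sp8_GOF cells had a construct UMI, against 6.51% (5.75 to 7.35) and 7.83% (7.0 to 8.72) of control cells. Control cells lack the allele and give the level of reads assigned to the construct without it, not that of free construct RNA in Sp8_GOF droplets. In Sp8_GOF replicate 2, trophoblast-like cells had a construct UMI in 14.4% (Clopper-Pearson interval 11.1 to 18.1; median depth 34733 UMIs) and erythroid-like cells in 29.1%. No class is known to lack the construct, so the Sp8_GOF shares can include free RNA. Unthinned, the shares were 66.6% and 42.3% against 14.3% and 21.4%. UMIs of the Sp8 gene (ENSMUSG00000048562, GRCm38 chromosome 12, 118846329 to 118852576, plus strand) numbered 320 and 65 in the Sp8_GOF libraries and 2 and 53 in the control libraries. Of the latter 53, 41 lay in the unnamed cluster 16, whose leading genes were Robo2, Tenm3 and Lef1. In erythroid-like cells Sp8 had 289 and 23 UMIs in the Sp8_GOF libraries against 2 and 4 in the control libraries.

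None of these differences in the construct or Sp8 passed the edgeR test across all genes of a class. The Sp8_GOF libraries differed widely from each other, and so did the embryos within each. The construct stood at 191 and 385 CPM in erythroid-like cells of the Xist and Y embryos of Sp8_GOF replicate 1. In those of replicate 2 it stood at 29.2 and 154 CPM. The construct's log2 fold change was 4.83 (SE 0.88, adjusted p = 0.48) in erythroid-like cells, 1.97 (SE 0.33, adjusted p = 0.90) in mesoderm-like cells, 1.83 (SE 0.26, adjusted p = 0.97) in progenitor-like cells and 0.94 (SE 0.49, adjusted p = 1.0) in endothelium-like cells. That of Sp8 was 5.97 (SE 1.16, adjusted p = 0.48) in erythroid-like cells. Sp8 passed without Sp8_GOF replicate 1 (4.19, adjusted p = 0.0043), without Sp8_GOF replicate 2 (6.70, adjusted p = 1.7e-07) and in DESeq2 (6.02, adjusted p = 7.0e-06). Without Sp8_GOF replicate 1 the erythroid value for the construct was 3.27 and without Sp8_GOF replicate 2 it was 5.54, and both passed the threshold, as did the DESeq2 Wald test at 4.82. With classes by highest marker score per cell the construct stood at 4.53 in erythroid-like, 4.56 in progenitor-like and 3.39 in endothelium-like cells. It was then 1.95 in mesoderm-like and 3.94 in endoderm-like cells, and none of these values passed. Without the clusters that hold no control cell the erythroid value was 2.13 (adjusted p = 0.39), beside 1.97 in mesoderm-like cells. In mesoderm-like cells it passed without Sp8_GOF replicate 1 (1.55, adjusted p = 0.0083), without Sp8_GOF replicate 2 (2.29, adjusted p = 0.00026) and in DESeq2 (1.96, adjusted p = 0.0029). In progenitor-like cells it passed likewise (1.62, adjusted p = 1.7e-06; 1.98, adjusted p = 3.9e-13; DESeq2 1.84, adjusted p = 0.017), and without a filter on low counts (1.84, adjusted p = 8.1e-10), as did the endoderm-like value (2.41, adjusted p = 0.0058). In endothelium-like cells it was 0.25 without Sp8_GOF replicate 1 and did not pass, and 3.80 (adjusted p = 0.016) with doublets kept, when a cluster without control cells took that name. Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729, plus strand) was tested in mesoderm-like cells alone, where it had 0.37 and 9.51 CPM in the Sp8_GOF libraries and 10.1 and 6.61 CPM in the control libraries. Its log2 fold change was -0.87 (SE 1.28, adjusted p = 0.95); without Sp8_GOF replicate 1 it was 0.15, and without Sp8_GOF replicate 2 it was -4.41 and passed the threshold.

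**Figure D1:**
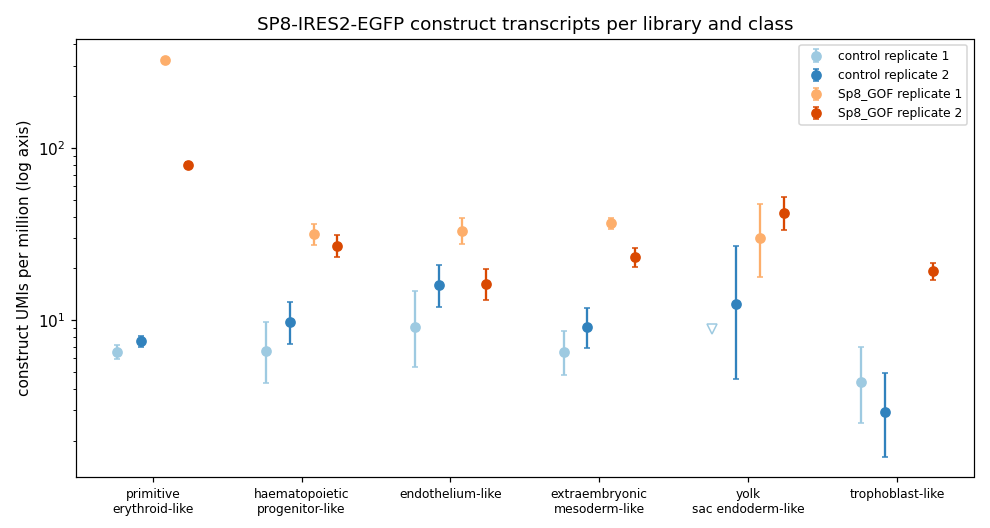
UMIs of the SP8-IRES2-EGFP construct in CPM on a log axis, by cell class; each point is 1 library, bars are exact Poisson intervals, and the open triangle marks the limit of 3 counts for a library with none. Erythroid-like cells of the Sp8_GOF libraries reached 326 and 79.6 CPM, while the control libraries lay at 6.56 and 7.54 CPM.

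Erythroid-like cells made up 65.6% (Clopper-Pearson interval 64.1 to 67.0) and 30.4% (28.7 to 32.1) of the Sp8_GOF libraries against 78.2% (76.9 to 79.5) and 71.8% (70.3 to 73.2) of the control libraries. Mesoderm-like cells made up 19.3% (18.2 to 20.6) and 12.1% (10.9 to 13.3) against 9.07% (8.18 to 10.0) and 5.59% (4.89 to 6.36). Endothelium-like cells made up 3.80% and 6.56% against 2.27% and 2.82%, progenitor-like cells 4.91% and 7.57% against 4.17% and 4.43%, and endoderm-like cells 0.496% and 2.79% against 0.443% and 0.461%. In each of these 5 classes both Sp8_GOF libraries lay on the same side of both control libraries, for which the exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Trophoblast-like cells, which do not belong to the yolk sac itself, were 0% and 13.9% of the Sp8_GOF libraries and 3.36% and 3.33% of the control libraries (exact permutation p = 1). Amnion or surface ectoderm-like cells were 0.236% and 1.14% against 0.235% and 0.487% (p = 0.667 by the same exact test). Allantois-like cells were 0.543% and 0.034% against 0% and 1.13% (p = 1 by the same exact test). With erythroid-like cells left out of the total, the difference in mean share was 0.027 points for endothelium-like cells in place of 2.64 points, and turned from 1.94 to -4.87 points for progenitor-like cells. Mesoderm-like cells were then 56.1% and 17.3% of the Sp8_GOF libraries against 41.7% and 19.8% of the control libraries, and endoderm-like cells 1.44% and 4.01% against 2.04% and 1.63% (exact permutation p = 1 for both classes). Amnion-like cells turned from 0.329 to -0.237 points and trophoblast-like cells from 3.58 to -3.67 points. At doubled clustering resolution the difference for progenitor-like cells was 0.065 points (exact permutation p = 1). By highest marker score per cell it was 8.94 points. For endothelium-like cells it was 7.25 points by marker score and 6.33 points with doublets kept. Dissection, dissociation and the sort for living cells can set all of these shares, and embryo stage was not separated from genotype. The Xist embryo of control replicate 2 had 49.5% erythroid-like cells, with 244 CPM of the globin gene Hbb-y in them. The other control embryos had 76.9% to 84.9%, with 1820 to 18086 CPM. Sp8_GOF replicate 1 embryos had 62.4% and 66.6% (2786 and 7629 CPM). Those of replicate 2 had 27.2% and 35.3% (155 and 738 CPM). Over all cells the construct stood at 140 and 275 CPM in the Xist and Y embryos of Sp8_GOF replicate 1. In those of replicate 2 it stood at 22.5 and 114 CPM. The Sp8_GOF embryo with the lowest erythroid-like share thus also had the lowest construct level. The unnamed cluster 9, closest to the primitive erythroid list, held a further 16.8% of Sp8_GOF replicate 2.

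Clusters 1, 6 and 17 held 2417 cells of the Sp8_GOF libraries and 0 of the control libraries. Cluster 1, erythroid-like and led by Sct, Mgarp and Eno3, held 1328 cells of Sp8_GOF replicate 1 and 19 of replicate 2. Cluster 6, erythroid-like and led by Nefh, Tnni1 and Ano2, held 727 and 95, and the unnamed cluster 17, led by Upp1, F5 and the platelet chemokine gene Pf4, held 138 and 110. The construct stood at 602 and 1056 CPM in cluster 1, 272 and 394 CPM in cluster 6, and 393 and 501 CPM in cluster 17; it had been left out of the clustering. At doubled resolution a cluster of 773 cells of Sp8_GOF replicate 1 and 4 of replicate 2, led by Sct, Fxyd7 and Capg and with the construct at 575 CPM, lost the erythroid name because its top genes held more markers of another list. Clusters of 528 and 12 and of 737 and 88 cells kept it, all without control cells, and the erythroid-like share of Sp8_GOF replicate 1 was then 49.0% in place of 65.6%. The other unnamed clusters held 0.547%, 3.90%, 0.708% and 16.8% of control replicates 1 and 2 and Sp8_GOF replicates 1 and 2 (cluster 9, led by Fgf3), 0.652%, 3.69%, 1.16% and 2.22% (cluster 16) and 1.02%, 2.41%, 0% and 2.89% (cluster 19, led by Id2). Of the mesoderm-like cells, cluster 3 held 290, 96, 810 and 24 cells in the same order of libraries, and cluster 14 held 12, 105, 9 and 301, so different clusters made up this class in the 2 Sp8_GOF libraries.

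**Figure D2:**
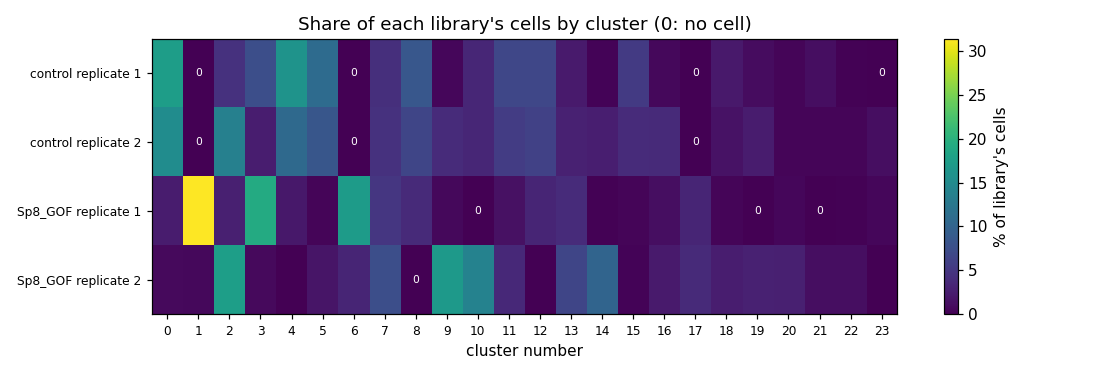
Share of each library's cells, in percent, that fell into each of 24 clusters; 0 marks clusters without a cell of that library. Clusters 1, 6 and 17 hold no control cell, and cluster 1 holds 1328 cells of Sp8_GOF replicate 1.

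In erythroid-like cells, genes of intraflagellar transport, the machinery that moves cargo along the cilium, rose as a list in Sp8_GOF. The median log2 fold change was 0.40, and 27 of 32 measured genes were positive (camera adjusted p = 0.013; adjusted p = 0.63 with an estimated correlation). Ift22 had a log2 fold change of 0.68 (SE 0.25), Tctex1d2 1.11 (SE 0.45), the kinesin gene Kif3a 0.71 (SE 0.30) and Ift46 0.92 (SE 0.40), with adjusted p from 0.498 to 0.534 for the 4 genes in edgeR. Genes of the ciliary membrane and its signalling also rose as a list, with a median of 0.28 and 19 of 23 positive (camera adjusted p = 0.013; adjusted p = 0.60 with an estimated correlation). Evc stood at 3.28 (SE 0.59), Tub at 1.31 (SE 0.38), Cys1 at 5.72 (SE 1.65) and Gpr161 at 1.57 (SE 0.57). The lists for the BBSome and transition zone (median 0.12, adjusted p = 0.105), basal body (0.07, adjusted p = 0.404), motile cilia (0.38, adjusted p = 0.505) and cilium disassembly (0.05, adjusted p = 0.631) did not pass. Adjusted over the list alone, 0 genes of the intraflagellar transport list and 0 of the ciliary membrane list passed. The intraflagellar transport call was lost without Sp8_GOF replicate 1 (median 0.12, adjusted p = 0.41), without control replicate 1 (adjusted p = 0.071) and without control replicate 2 (adjusted p = 0.081). It was also lost without the clusters that hold no control cell (median 0.06, adjusted p = 0.53). The call for ciliary membrane and signalling was lost without Sp8_GOF replicate 1 (adjusted p = 0.07), without control replicate 1 (adjusted p = 0.056) and without those clusters (median 0.11, adjusted p = 0.52). For Sp, Rfx and Foxj1 factors the median was -0.05, the mean 0.45 and the test direction down (adjusted p = 0.985).

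The same cells had higher levels of BMP targets, read-outs of bone morphogenetic protein signalling, with a median of 1.68 and 10 of 11 genes positive (camera adjusted p = 0.00015; adjusted p = 0.60 with an estimated correlation). Id1 stood at 2.01 (SE 0.39), Bmper at 2.49 (SE 0.49), Msx2 at 1.76 (SE 0.40) and the haematopoietic factor gene Gata2 at 3.38 (SE 0.76), and 5 genes rose when adjusted over the list alone. Tubulins had a median of 0.42 with 11 of 11 positive (adjusted p = 0.0053; adjusted p = 0.60 with an estimated correlation). Tuba1a stood at 2.44 (SE 0.66) and Tubb3 at 2.02 (SE 0.67). Targets of the tumour suppressor p53 had a median of 0.58 (adjusted p = 0.0031; adjusted p = 0.60 with an estimated correlation). The cell cycle inhibitor Cdkn1a stood at 1.39 (SE 0.24) and the receptor gene Eda2r at 1.21 (SE 0.24). Mitochondrially encoded transcripts fell, with a median of -0.59 and 0 of 13 positive (adjusted p = 1.2e-06; adjusted p = 0.60 with an estimated correlation). Among these mt-Nd6 stood at -1.21 (SE 0.15) and mt-Nd3 at -0.76 (SE 0.16). Primitive erythroid markers fell, with a median of -0.61 (adjusted p = 0.00074; adjusted p = 0.63 with an estimated correlation). The erythroid regulator Klf1 stood at -0.56 (SE 0.16) and Alas2, the first enzyme of haem synthesis in red cells, at -0.79 (SE 0.25). The globin genes stood at -1.48 (SE 0.53, Hba-a2) and -1.28 (SE 0.55, Hba-a1). Genes of haem synthesis and iron fell, with a median of -0.15 (adjusted p = 0.0053; adjusted p = 0.64 with an estimated correlation). The transferrin receptor gene Tfrc stood at -0.81 (SE 0.15), Cpox at -0.89 (SE 0.19), Slc25a37 at -0.87 (SE 0.18) and Alad at -0.60 (SE 0.16). Without Sp8_GOF replicate 2 the calls were lost for mitochondrial transcripts (median -0.19, adjusted p = 0.075), primitive erythroid markers (-0.20, adjusted p = 0.14), haem synthesis and iron (0.02, adjusted p = 0.47) and p53 targets (0.35, adjusted p = 0.18).

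Markers of some other tissues also rose as lists in erythroid-like cells, and those of others did not. Such transcripts can reach these cells as free RNA, and mesoderm-like and endothelium-like cells made up more of both Sp8_GOF libraries. Free RNA may add to these changes. Fewer lists of this class passed with genes low against another class left out. That step takes out markers of other tissues by its own rule, so the smaller number cannot show whether free RNA contributed. Endothelium markers had a median of 1.05 with 10 of 10 positive (camera adjusted p = 0.00014; adjusted p = 0.60 with an estimated correlation). Ramp2 stood at 2.53 (SE 0.48), the VEGF receptor gene Kdr at 1.72 (SE 0.35), Egfl7 at 0.80 (SE 0.24) and Flt1 at 1.28 (SE 0.43). Endoderm transcription factors (median 2.24, adjusted p = 0.00074), mesenchymal genes (1.05, adjusted p = 0.0045) and extraembryonic mesoderm markers (0.14, adjusted p = 0.0495) rose as well. Yolk sac endoderm markers had a median of -0.16 with 0 of 6 positive (adjusted p = 0.490) and macrophage markers a median of 0.22 (adjusted p = 0.779), and neither list passed. Interferon response genes rose (0.87, adjusted p = 0.020). The 4 of these lists that rose had an adjusted p of 0.60 with an estimated correlation. The list of dissociation stress and immediate early genes passed at a median of 0.60 with 16 of 19 positive (camera adjusted p = 0.0495, and adjusted p = 0.71 with an estimated correlation). Atf3 stood at 4.50 (SE 1.43), Nr4a1 at 2.60 (SE 0.79) and Ier3 at 1.55 (SE 0.58), but Egr1 at -2.11 (SE 0.15). Without Sp8_GOF replicate 1 the calls were lost for endoderm transcription factors (median 0.62, adjusted p = 0.069), interferon response (0.38, adjusted p = 0.31) and extraembryonic mesoderm markers (0.66, adjusted p = 0.23). The call for dissociation stress and immediate early genes was lost too (0.11, test direction down, adjusted p = 0.50). Without Sp8_GOF replicate 2 they were lost for endothelium markers (1.08, adjusted p = 0.12), mesenchymal genes (0.53, adjusted p = 0.46) and extraembryonic mesoderm markers (0.53, adjusted p = 0.30). Without control replicate 2 extraembryonic mesoderm markers (-0.13, adjusted p = 0.80) and dissociation stress and immediate early genes (0.49, adjusted p = 0.081) did not pass.

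At the level of single genes, edgeR called 0 of 15546 genes higher and 0 lower in erythroid-like cells, with 1552 at an unadjusted p under 0.05, while DESeq2 called 360 higher and 71 lower. Without Sp8_GOF replicate 1 edgeR called 835 and 955, without Sp8_GOF replicate 2 it called 3894 and 3524, and without either control library 0 and 0. In the added fit of sums per embryo, 4 embryos of each genotype and 2 of each library, 1 gene was higher and 0 were lower, with 2636 at an unadjusted p under 0.05. That gene was Lgr5, a Wnt target, at a log2 fold change of 6.21 (SE 0.52, edgeR adjusted p = 0.042), named after its value was seen. In the fit of library sums without the clusters that hold no control cell the counts were again 0 and 0. The sums per embryo were not fitted without those clusters. The embryos differed in globin transcripts within each genotype: erythroid-like cells of the 4 control embryos had 18086, 1820, 244 and 5738 CPM of the embryonic globin gene Hbb-y, and those of the 4 Sp8_GOF embryos 2786, 7629, 155 and 738 CPM.

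**Figure D3:**
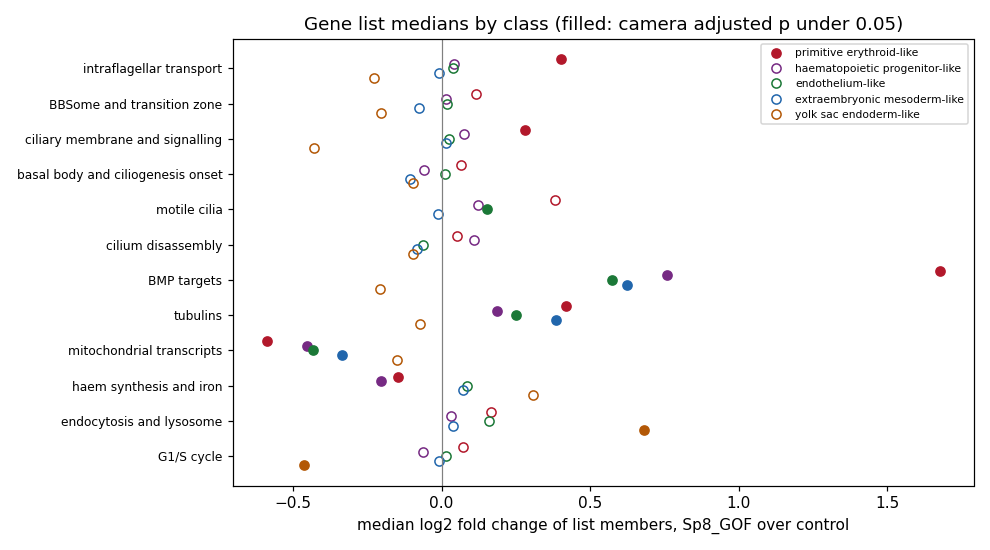
Median log2 fold change of Sp8_GOF over control of each gene list (vertical axis) by cell class (colour); filled points passed camera at an adjusted p under 0.05. Intraflagellar transport lies at 0.40 in erythroid-like cells and between -0.23 and 0.04 in the other 4 classes, and BMP targets lie at 0.57 or above in the classes other than endoderm-like cells.

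In extraembryonic mesoderm-like cells, BMP targets rose as a list, with a median log2 fold change of 0.62 and 11 of 12 genes positive (camera adjusted p = 2.1e-12; adjusted p = 0.53 with an estimated correlation). Bmper, a secreted modulator of BMP signalling, stood at 2.87 (SE 0.58), Id2 at 0.74 (SE 0.16), and the homeobox genes Msx1 at 0.58 (SE 0.18) and Msx2 at 0.59 (SE 0.19). Tubulins had a median of 0.38 with 11 of 11 positive (adjusted p = 9.1e-08; adjusted p = 0.36 with an estimated correlation), led by Tuba1a at 0.56 (SE 0.11). Mitochondrially encoded transcripts had a median of -0.33 with 0 of 13 positive (adjusted p = 7.3e-09; adjusted p = 0.36 with an estimated correlation), among them mt-Nd6 at -0.89 (SE 0.17). Primitive erythroid markers, which mesoderm cells do not make and which can reach them as free RNA, had a median of -1.74 (adjusted p = 2.1e-12; adjusted p = 0.36 with an estimated correlation). Hba-a2 stood at -2.53 (SE 0.41) and Klf1 at -2.65 (SE 0.60). Dissociation stress genes (median 0.19, adjusted p = 0.00037), p53 targets (0.34, adjusted p = 0.0027) and G2/M genes (-0.10, adjusted p = 0.029) passed too, with adjusted p = 0.53, 0.95 and 0.73 with an estimated correlation. Adjusted over the list alone, 2 BMP targets and 1 tubulin rose and 2 erythroid markers and 1 mitochondrial transcript fell. The p53 targets lost their call without Sp8_GOF replicate 2 (median -0.30, adjusted p = 0.48), and dissociation stress and immediate early genes without control replicate 2 (0.09, adjusted p = 0.23). The G2/M cycle genes lost theirs without control replicate 2 (-0.12, adjusted p = 0.29), Sp8_GOF replicate 1 (-0.13, adjusted p = 0.31) or Sp8_GOF replicate 2 (-0.16, adjusted p = 0.079).

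Intraflagellar transport genes of mesoderm-like cells had a median of -0.01 with 15 of 31 positive (adjusted p = 0.871). Ift43 stood at 0.26 (SE 0.10), Ift88, a core component of the transport complex, at -0.43 (SE 0.19), Ttc21b at -0.37 (SE 0.16) and Dync2li1 at 0.44 (SE 0.19). The other cilia lists had medians of -0.08 (BBSome and transition zone), 0.01 (ciliary membrane), -0.11 (basal body), -0.01 (motile cilia) and -0.08 (cilium disassembly) and did not pass. The difference between the erythroid and mesoderm effects, tested as an interaction added after the data were examined, passed for 0 genes in edgeR, with 1001 at an unadjusted p under 0.05. It passed for 993 genes without Sp8_GOF replicate 1 and for 4202 without Sp8_GOF replicate 2. Among single genes of mesoderm-like cells, edgeR called 0 of 12750 higher and 0 lower, with 627 at an unadjusted p under 0.05. DESeq2 called 4 and 1. Without Sp8_GOF replicate 1 edgeR called 105 and 112, and without Sp8_GOF replicate 2 it called 51 and 54.

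In haematopoietic progenitor-like cells BMP targets rose with a median of 0.76 and 8 of 8 genes positive (camera adjusted p = 1.9e-05; adjusted p = 0.71 with an estimated correlation). Id1 stood at 0.74 (SE 0.13), Msx1 at 1.33 (SE 0.48), and the inhibitory Smad genes Smad7 at 0.49 (SE 0.29) and Smad6 at 1.12 (SE 0.86). Without Sp8_GOF replicate 2 the BMP targets had a median of -0.07 (adjusted p = 0.27). The make-up of this class differed between libraries, since 74, 65, 115 and 30 cells were named progenitor-like at doubled clustering resolution in place of 160, 173, 208 and 225. Tubulins rose with a median of 0.19 (adjusted p = 0.0057; adjusted p = 0.71 with an estimated correlation). Mitochondrially encoded transcripts fell with a median of -0.45 and 0 of 13 positive (adjusted p = 4.1e-13; adjusted p = 0.71 with an estimated correlation), among them mt-Nd6 at -0.90 (SE 0.18) and mt-Nd3 at -0.49 (SE 0.10). Primitive erythroid markers (median -0.64, adjusted p = 4.4e-05) and genes of haem synthesis and iron (median -0.20, adjusted p = 0.0045) fell as well, both with an adjusted p of 0.71 with an estimated correlation. Slc25a37, the mitochondrial iron importer, stood at -0.90 (SE 0.15), Cpox at -0.58 (SE 0.12) and Alas2 at -0.61 (SE 0.23). The call for haem synthesis and iron was lost without control replicate 1 (median -0.04, adjusted p = 0.23) and without Sp8_GOF replicate 2 (0.04, adjusted p = 0.46), and that for tubulins without control replicate 1 (0.24, adjusted p = 0.13). Intraflagellar transport genes had a median of 0.04 with 18 of 30 positive (adjusted p = 0.527). Single genes called by edgeR numbered 0 higher and 0 lower of 11276, with 403 at an unadjusted p under 0.05, and DESeq2 called 3 and 1. Without Sp8_GOF replicate 1 the edgeR counts were 366 and 574, and without Sp8_GOF replicate 2 they were 318 and 162.

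In endothelium-like cells BMP targets rose with a median of 0.57 and 7 of 8 genes positive (camera adjusted p = 4.6e-05; adjusted p = 0.71 with an estimated correlation). Of the inhibitors of basic helix-loop-helix factors, Id2 stood at 1.18 (SE 0.34), Id3 at 0.56 (SE 0.21) and Id1 at 0.80 (SE 0.35). Without Sp8_GOF replicate 2 the median of the BMP targets was -0.08 (adjusted p = 0.56) and without control replicate 1 it was 0.07 (adjusted p = 0.73). At doubled clustering resolution endothelium-like cells formed a cluster led by Flt1, with 17, 86, 34 and 187 cells, and another led by Lyve1, with 70, 24, 126 and 8, so libraries drew on different endothelium-like clusters. Tubulins had a median of 0.25 (adjusted p = 0.0015), with Tubb2b at 0.80 (SE 0.25) and Tubb3 at 1.93 (SE 0.61). Mitochondrially encoded transcripts had a median of -0.43 with 0 of 13 positive (adjusted p = 4.3e-10), among them mt-Nd5 at -0.48 (SE 0.16) and mt-Nd1 at -0.58 (SE 0.20). Motile cilia genes passed with a median of 0.15 and 5 of 6 positive (adjusted p = 0.045), among them Cfap43 at 1.38 (SE 0.38), with Gas8 at 0.12 (SE 0.22) and Dnaic1 at -0.37 (SE 1.01). Without control replicate 2 the median of the motile cilia list was 0.05 with the test pointing down (adjusted p = 0.98). Its call was also lost without Sp8_GOF replicate 1 (0.67, adjusted p = 0.056) or Sp8_GOF replicate 2 (0.44, adjusted p = 0.56). Tubulins did not pass without control replicate 2 (0.14, adjusted p = 0.13) or Sp8_GOF replicate 1 (0.08, adjusted p = 0.58). Erythroid markers (median -1.24), stress genes (0.14), cholesterol synthesis (0.19), p53 targets (0.15) and G2/M genes (-0.12) passed at adjusted p = 0.00051, 0.0021, 0.0053, 0.0053 and 0.0053. Calls were lost without control replicate 1 for primitive erythroid markers (0.24, adjusted p = 0.81), dissociation stress and immediate early genes (0.13, adjusted p = 0.73), p53 targets (0.15, adjusted p = 0.71) and G2/M cycle genes (-0.18, adjusted p = 0.080). They were lost without Sp8_GOF replicate 2 for primitive erythroid markers (-0.40, adjusted p = 0.76), p53 targets (-0.02, adjusted p = 0.76) and cholesterol synthesis (0.13, adjusted p = 0.49). Without control replicate 2 the losses were cholesterol synthesis (0.18, adjusted p = 0.35) and G2/M cycle genes (-0.14, adjusted p = 0.085), and without Sp8_GOF replicate 1 they were dissociation stress and immediate early genes (0.18, adjusted p = 0.056) and G2/M cycle genes (-0.09, adjusted p = 0.48). All 9 lists that passed in this class had an adjusted p of 0.71 with an estimated correlation. Intraflagellar transport genes had a median of 0.04 with 16 of 29 positive (adjusted p = 0.564), and basal body genes a median of 0.01 and a mean of -0.02 with the test pointing down. Single genes called by edgeR numbered 0 higher and 0 lower of 10829, with 140 at an unadjusted p under 0.05, and DESeq2 also called 0 and 0.

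The yolk sac endoderm-like class, fitted with 17, 18, 21 and 83 cells as an addition made after the data were examined, had higher levels of genes of uptake and secretion. Genes of endocytosis and lysosome had a median log2 fold change of 0.68 with 21 of 24 positive (camera adjusted p = 4.2e-11; adjusted p = 0.67 with an estimated correlation). The cathepsin gene Ctsc stood at 1.39 (SE 0.22) and Ctsz at 1.02 (SE 0.23), and the vitamin B12 receptor genes Amn at 1.51 (SE 0.29) and Cubn at 1.07 (SE 0.21). Of this list 9 rose when adjusted over the list alone. Genes of lipoprotein and lipid transport had a median of 0.76 (adjusted p = 3.6e-05), with Apoe at 1.48 (SE 0.28), Apob at 1.28 (SE 0.35), Soat2 at 1.23 (SE 0.37) and Mttp at 0.75 (SE 0.22). Secreted serum protein genes had a median of 1.16 with 13 of 13 positive (adjusted p = 1.5e-05). The coagulation genes F10 and Fga stood at 1.36 (SE 0.45) and 1.72 (SE 0.59). Yolk sac endoderm markers had a median of 1.03 (adjusted p = 1.5e-06). Genes of the unfolded protein response had a median of 0.24 (adjusted p = 0.015). G1/S genes fell with a median of -0.46 and 1 of 23 positive (adjusted p = 1.5e-06), among them Rrm2 at -1.18 (SE 0.22) and Mcm3 at -0.70 (SE 0.25), both needed for DNA replication. Wnt targets fell with a median of -0.96 (adjusted p = 0.019), among them Ccnd1 at -2.74 (SE 0.54), while Dkk1 of the same list stood at 1.56 (SE 0.49). These 6 lists also had an adjusted p of 0.67 with an estimated correlation.

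Intraflagellar transport genes of endoderm-like cells had a median of -0.23 with 4 of 12 measured genes positive (adjusted p = 0.425), among them Ift57 at -1.29 (SE 0.46) and Ift20 at 0.56 (SE 0.23). The construct stood at 2.35 (SE 0.68, adjusted p = 0.36), and control replicate 1 held 0 construct UMIs in this class. Without control replicate 1 the value was 1.58, and without control replicate 2 it was 8.22, which is fitted against a library with 0 counts and is no bound. Single genes called by edgeR numbered 0 higher and 0 lower of 7034, with 695 at an unadjusted p under 0.05, and DESeq2 called 12 and 11. Without Sp8_GOF replicate 1 the edgeR counts were 11 and 15, without Sp8_GOF replicate 2 they were 12 and 7, and without control replicate 1 they were 0 and 3. Without control replicate 2 the secreted serum proteins (median 0.61, adjusted p = 0.26), the yolk sac endoderm markers (0.29, adjusted p = 0.25), the unfolded protein and amino acid response (0.15, adjusted p = 0.50) and the Wnt targets (0.85, adjusted p = 0.69) did not pass. Without Sp8_GOF replicate 2 the unfolded protein and amino acid response did not (0.20, adjusted p = 0.14).

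Cycling and quality measures overlapped between genotypes over all cells for G2/M transcripts, and not for the mitochondrial share. At 10000 UMIs per cell, the mean number of UMIs of G2/M genes was 36.2 and 33.9 in the control libraries and 34.1 and 38.9 in the Sp8_GOF libraries; unthinned it was 91.1, 110, 93.6 and 127. The median mitochondrial share of UMIs was 2.43% and 2.14% in the control libraries and 2.01% and 1.47% in the Sp8_GOF libraries. Median genes per cell were 4563 and 5086 against 4705 and 5550.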

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

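The tests of the construct reads in control libraries and of the difference between the endoderm and mesoderm effects were chosen after the data were examined.

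UMIs of the rtTA-EGFP feature, named after the doxycycline-dependent transactivator that per the labels both genotypes carry, lie outside the main comparisons. They were counted because they exceeded those of the control libraries. The feature took 493 UMIs in Sp8_GOF replicate 1 and 83 in Sp8_GOF replicate 2, against 0 and 1 in the control libraries. In the Xist and Y embryos of Sp8_GOF replicate 1 it took 81 and 384 UMIs beside 4835 and 19618 construct UMIs. In those of replicate 2 it took 12 and 69 beside 1330 and 3427. Since the control libraries carry the same allele, construct reads may be counted under this feature. Its UMIs were not taken as the level of the transactivator.

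The SP8-IRES2-EGFP construct took 1579 UMIs in the control libraries, which lack the allele. Molecules carried over from the Sp8_GOF libraries would have brought rtTA-EGFP with them at 1.87 per 100 construct UMIs, or 29.6 UMIs with a lower bound of 19.9, and the control libraries held 1, which argues against carry-over as the whole source. The control embryos carry the rtTA-EGFP allele, per the labels, so reads of sequence it shares with the construct may instead be counted under the construct. Among control classes with at least 20 construct UMIs, the ratio of the highest to the lowest CPM was 3.79 (endothelium-like 13.6, trophoblast-like 3.58; allantois-like cells held 14.7 CPM on 17 UMIs), which leaves shared sequence open, since the feature sequences are not given in the sources used here. No biological explanation was tested.

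The effect of Sp8_GOF differed between endoderm-like and mesoderm-like cells by an interaction test with library as a block. It passed for 56 of 12812 genes in edgeR, 13 with a higher and 43 with a lower change in endoderm-like cells, with 1003 at an unadjusted p under 0.05. The 5 genes with the smallest p, singled out after their values were seen, included the chaperone gene Cryab at -5.64 (SE 0.64), Limch1 at -3.37 (SE 0.41), the neural and mesenchymal factor gene Sox11 at -2.33 (SE 0.29), the growth regulator Hmga2 at -1.69 (SE 0.21) and the cyclin gene Ccnd2 at -2.42 (SE 0.30). The count was 163 without Sp8_GOF replicate 1, 96 without control replicate 1, 60 without Sp8_GOF replicate 2 and 50 without control replicate 2, and 0 without the library block (892 at an unadjusted p under 0.05). The endoderm-like class held 17, 18, 21 and 83 cells, and the mesoderm-like class drew on different clusters in the 2 Sp8_GOF libraries, so a change in cell make-up was not separated from a change within cells.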

How the results depend on the processing

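The fit of endoderm-like cells, the interactions, the sums per embryo, the comparison without clusters that hold no control cell and the construct-high against construct-low comparison were chosen after the data were examined. Over all alternatives, 1901 values for single named genes kept their direction and side of the threshold, 186 newly passed and 11 turned in direction; of the list medians 336 kept both, 66 no longer passed, 11 turned, 3 moved and 1 newly passed. None of these genes passed in the main fits, so keeping the side of the threshold meant still not passing. Most were list members picked for the smallest p in these data, so the gene counts are no measure of robustness. Except where the construction is named, the cause was not tested.

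Without a filter on low counts, edgeR called 6 genes higher and 2 lower in endothelium-like cells, 4 and 1 in mesoderm-like, 29 and 28 in progenitor-like and 92 and 79 in endoderm-like cells, and 163 in the endoderm interaction. With replicate number as a block, a pairing the labels do not explain, it called 58 and 42 in endothelium-like, 9 and 5 in progenitor-like, 60 and 17 in erythroid-like and 1 lower in endoderm-like cells. With this block Sp8 passed in erythroid-like cells (5.54, adjusted p = 0.024) and the construct in progenitor-like cells (1.81, adjusted p = 0.021). The correlations behind the pairing were 0.571, 0.38, 0.31, 0.21 and 0.182 in endothelium-like, mesoderm-like, progenitor-like, erythroid-like and endoderm-like cells. With doublets kept, 16 genes were higher in endothelium-like cells, where a cluster without control cells then took that name. DESeq2 called 4 and 1 in mesoderm-like, 3 and 1 in progenitor-like, 360 and 71 in erythroid-like and 12 and 11 in endoderm-like cells, and the construct passed at 4.82. Doubled clustering resolution gave 1 gene higher in progenitor-like cells, and sums per embryo 1 in erythroid-like cells. The endoderm interaction gave 0 genes without the library block.

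With an estimated correlation, and with fry, 0 lists passed in each class, in place of 9 in endothelium-like, 7 in mesoderm-like, 5 in progenitor-like, 14 in erythroid-like and 7 in endoderm-like cells. With genes low against another class left out, 4 lists passed in mesoderm-like, 1 in progenitor-like and 9 in erythroid-like cells; by highest marker score 9 passed in progenitor-like cells, and without clusters that hold no control cell 8 in erythroid-like cells.

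In endothelium-like cells the motile cilia median was 0.068 without a filter, with the test direction turned, the primitive erythroid markers stood at 0.50 by marker score, and Gas8 at -0.17 with doublets kept. By marker score in progenitor-like cells the erythroid markers stood at 0.17, haem synthesis and iron at 0.24, Alas2 at 0.071, Ift172 at 0.10 and Slc25a37 at 0.16, and Smad7 at -0.026 with doubled resolution. By marker score in endoderm-like cells the Wnt targets stood at 0.44 and Ift57 at 0.13. The erythroid stress list stood at 0.12 without clusters that hold no control cell, with the test direction turned.

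The difference in share was 0.988 points by marker score and -1.18 without erythroid-like cells for allantois-like cells (-0.276 as reported), 2.10 by marker score and -0.237 without erythroid-like cells for amnion-like cells (0.329), 1.75 by marker score and -3.67 without erythroid-like cells for trophoblast-like cells (3.58), 6.33 with doublets kept, 7.25 by marker score and 0.027 without erythroid-like cells for endothelium-like cells (2.64), and 8.94 by marker score, -4.87 without erythroid-like cells and 0.065 at doubled resolution for progenitor-like cells (1.94). Construct-high against construct-low cells gave 1124 and 1125 genes at 3 or more against 0 UMIs and 1115 and 1173 with the library as unit.

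Leaving out 1 library, the lone library of its group being assumed to vary like the other group, gave 0 to 105 genes higher and 0 to 112 lower in mesoderm-like cells, 0 to 366 and 0 to 574 in progenitor-like, 0 to 3894 and 0 to 3524 in erythroid-like and 0 to 12 and 0 to 15 in endoderm-like cells, 50 to 163 in the endoderm interaction and 0 to 4202 in the erythroid interaction. Lists passing ranged from 3 to 11 in progenitor-like, 8 to 13 in erythroid-like and 3 to 9 in endoderm-like cells. In endothelium-like cells the motile cilia median ranged from 0.046 to 0.67, the primitive erythroid markers from -3.18 to 0.24, Dnaic1 from -1.74 to 0.58 and Smad7 from -0.28 to 2.46. The p53 targets of mesoderm-like cells ranged from -0.30 to 0.76 and Sp5 there from -4.41 to 0.15, Smad6 of progenitor-like cells from -0.28 to 2.13, the erythroid stress list from 0.11 to 1.06, and the endoderm Wnt targets from -1.61 to 0.85. The construct in erythroid-like cells ranged from 3.27 to 5.54, and leaving out 1 embryo gave 421 to 2481 genes higher and 376 to 2656 lower in construct-high cells.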

Other observations

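The comparison of construct-high with construct-low cells, the scaling of maturity to erythroid markers, the sums per embryo and the tests on clusters without control cells were chosen after the data were examined; the tests of swapped states, of splits of the embryos, of maturity and of RNA from other cell types had their outcomes set down before their results were seen.

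Within Sp8_GOF embryos, erythroid-like cells with at least 5 construct UMIs had higher levels of intraflagellar transport genes than those with at most 1. Of 31 genes 13 rose and 2 fell, with a median log2 difference of 0.37 (camera adjusted p = 0.0011; adjusted p = 0.84 with an estimated correlation), among them Ift46 at 1.20 (SE 0.19), Wdr60 at 1.16 (SE 0.18), Kif3a at 0.87 (SE 0.14) and Ift80 at 1.07 (SE 0.18). Dissociation stress and immediate early genes were higher (median 0.77, 14 rose and 1 fell of 19, adjusted p = 3.7e-06), as were endoderm transcription factors (2.33, 4 of 6 rose, adjusted p = 0.0058), with Jun at 0.85 (SE 0.10), Fos at 1.52 (SE 0.22), Foxa1 at 2.74 (SE 0.47) and Gata4 at 2.00 (SE 0.53). Primitive erythroid markers were lower (median -0.58, 5 of 10 fell, adjusted p = 0.00012), with Hba-a1 at -1.19 (SE 0.09) and Klf1 at -0.99 (SE 0.11); these 3 lists also had an adjusted p of 0.84 with an estimated correlation. The lists for the ciliary membrane (0.19, adjusted p = 0.176), BBSome and transition zone (0.26, adjusted p = 0.115), basal body (0.16, adjusted p = 0.105), BMP targets (1.08, adjusted p = 0.092), motile cilia (0.64, 13 of 14 positive, adjusted p = 0.098) and mitochondrial transcripts (median 0.14) did not pass. Of 20 genes of the ciliary membrane list 13 were positive, 6 rose and 1 fell. The ciliary genes Cys1 at 2.71 (SE 0.42) and Arl13b at 0.65 (SE 0.14) were higher. The feature rtTA-EGFP-3XSV40polyA-PGKpolyA was 6.39 (SE 0.45) higher. Reads of the construct may be counted under that feature.

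The 4 embryos held 285, 1131, 21 and 92 high and 369, 521, 402 and 224 low cells, and edgeR with embryo as a block called 1802 genes higher and 2232 lower of 12483. Leaving out 1 embryo gave 421 to 2481 higher and 376 to 2656 lower. Intraflagellar transport genes that rose numbered 5 without the Xist embryo of Sp8_GOF replicate 1, 8 without its Y embryo and 8 without the Y embryo of Sp8_GOF replicate 2, in place of 13. Without the Xist embryo of Sp8_GOF replicate 1, 5 stress genes rose in place of 14, 3 erythroid markers fell in place of 5 and 2 endoderm transcription factors rose in place of 4, as they did without the Y embryo of Sp8_GOF replicate 2. The lists for motile cilia and BMP targets passed without the Xist embryo of Sp8_GOF replicate 1 (0.76 and 0.96, both adjusted p = 0.042) and without its Y embryo (0.64 and 0.74, both adjusted p = 0.045). Motile cilia also passed at 3 or more against 0 UMIs (0.86, adjusted p = 0.033), BMP targets with library as the unit (1.01, adjusted p = 0.031), and basal body at 10 or more against 0 UMIs (0.26, adjusted p = 0.044) and after genes low against another class were removed (0.20, adjusted p = 0.034). The 4 lists that passed with all embryos did so without any 1 of them, and that for endoderm transcription factors was lost without a filter on low counts (0.47, adjusted p = 0.094). Among 8 assignments of the states within embryos, which are too few for a share under 0.05, 1 gave as many genes, the real one with 4034, and the highest other gave 53.

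Erythroid maturity was set against construct level as an explanation for the higher intraflagellar transport genes. From control cells lowest in Hbb-y share to those highest, the other 9 erythroid markers rose by a median of 0.47, about as far as they fell from low to high cells (-0.46), while the called genes moved by -0.01 (SD 0.145), against 0.87 between high and low cells. This argues against maturity of that kind as the whole difference; the product set down in advance came to -0.00049 of it but is weak by itself, since its slope was near 0 (0.034, r = 0.011). RNA from other cell types may add to the difference. Of the 13 called genes, 10 (0.769) were left after genes low against another class were removed, and all 10 were still called. The removed genes were not tested there, so this does not settle it. The cells were split by a transcript of the construct itself, so Sp8 and whatever opens the locus cannot be separated here, and an effect of Sp8 itself was not tested.

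Over erythroid-like and progenitor-like cells and the unnamed clusters 9 and 17, the clusters without control cells (1, 6 and 17) held 96.5% of the construct-high cells of Sp8_GOF replicate 1 and 78.1% of those of replicate 2, against 31.1% and 1.70% of the construct-low cells. Over erythroid-like cells alone, clusters 1 and 6 held 97.1% and 76.3% against 36.2% and 1.53%. At doubled clustering resolution a cluster without control cells lost the erythroid name. A difference in cell type between construct-high and construct-low cells was therefore not separated from a change within erythroid-like cells.

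A difference between whole libraries would place high and low cells alike in the clusters without control cells, but the higher ratio of low to high shares was 0.322, which argues against it. Doublets would often join both embryos of a library, while 1.90% of cells in these clusters (upper bound 2.53%) held Xist with Y-linked transcripts, against 41.7% and 46.7% of random pairs. Handling stress of whole libraries may still contribute, with a stress median of up to 0.19 in the other 3 classes. A change of state brought about by Sp8 was not tested.

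Sums per embryo, 4 against 4 with a sex term, gave 1 gene in erythroid-like cells (Lgr5). The embryos sit 2 to a library and are not independent of it. Of 34 splits of the 8 embryos, 1 gave as many genes, the real one, and the highest other gave 0. Whole libraries can be split in 3 ways, too few for a share under 0.05, and the count rests on 1 gene. In mesoderm-like, endothelium-like and progenitor-like cells edgeR called 0 genes, with 1358, 419 and 741 at an unadjusted p under 0.05; DESeq2 was not run on these sums. Erythroid-like cells made up 80.2%, 76.9%, 49.5% and 84.9% of the control embryos and 62.4%, 66.6%, 27.2% and 35.3% of the Sp8_GOF embryos, and trophoblast-like cells 0%, 5.26%, 8.71% and 0% of the control embryos and 0%, 0%, 21.7% and 0% of the Sp8_GOF embryos.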
